A study of Homo sapiens with 6 samples.

How the data were processed

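RNA was measured in 6 samples, 3 from each of 2 human colon cancer cell lines. The lines are SW480 and SW620, established from a primary colon tumour and from a later lymph node metastasis of the same cancer. Per the labels, cell lysates were run on sucrose gradients in an ultracentrifuge and the fractions that hold polysomes were kept. Polysomes are mRNAs carrying several ribosomes. Polysomal RNA alone reflects both how much of an mRNA a cell holds and how much of it is being translated, and these cannot be separated without unfractionated RNA, which was not analysed here. The replicate numbers come from the sample titles. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

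The deposited values are intensities, 1 signal per probe set on a linear scale, from Affymetrix GeneChip human genome arrays per the file headers. The software that made them is not given in the sources used here. The mean after leaving out the lowest and highest 2% of probe sets was 100.04 on every array, so the deposited intensities were taken as scaled by the authors to a common mean and were not normalised again. The experiment files deposited with the arrays hold scanner and fluidics settings. They were used only for the wash run and the fluidics module of each array. A new wash run was set where washes lay more than 10 minutes apart, which gave 2 runs. The first run held SW480 replicates 1 and 2 and SW620 replicate 1, and the other held SW480 replicate 3 and SW620 replicates 2 and 3. Each of 3 fluidics modules washed 1 array of each line.

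Each array held 22283 probe sets, of which 68 were array controls and were left out of the tests. Of the other 22215, 19065 had 1 gene symbol in the platform annotation, 1043 had several and 2107 had none. No gene was named from a set with several symbols. Of the sets with 1 symbol, 19053 matched a gene of the RefSeq annotation of assembly GRCh38.p14 by Entrez ID, which gave the chromosome and the order of neighbouring genes. No coordinate is printed, because the build behind the array design is not given in the sources used here.

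Signals were put on the scale log2(signal + 8), where 8 is the pooled 25th percentile of the values. A fold change on this scale understates the change of dim genes. Probe sets in the lowest 40% by mean over all 6 samples were left out, a limit near a signal of 16.1, and 13329 were tested. For genes, the probe set with the highest mean among those with 1 symbol was used, and 8076 genes were tested. The lines were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with a trend, two-sided) with Benjamini-Hochberg adjustment. A call means an adjusted p under 0.05. Errors beside log2 fold changes are standard errors of the fit, and errors beside signals are SDs, with n = 3 per line. Control ratios were compared by a two-sided exact permutation test, which cannot go below 0.1 with 3 against 3.

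The gene lists, 36 in number with 1319 genes, were fixed before the data were examined, as were the main tests and the rule for named genes. They covered the translation apparatus (cytosolic ribosomal proteins; translation factors and TOP mRNAs outside the ribosome; translational control and mTOR signalling; aminoacyl-tRNA synthetases; ribosome biogenesis), growth and signalling, adhesion, differentiation, the cell cycle, immunity, metabolism, protein folding and turnover, and markers of leukocytes, fibroblasts, endothelium and neurons. TOP mRNAs are those whose translation follows mTOR through a tract at the start of the mRNA. A member counts as measured if a probe set with its symbol alone passed the filter on dim sets. At least 5 measured members were needed, which 35 lists had. Of the listed genes 891 were tested, and 28 of the tested genes stood on more than 1 list. Lists and chromosomes were tested with camera from limma at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists or chromosomes. Camera asks whether the genes of a set shift relative to all other genes. The same test with a correlation estimated from the residuals, and fry, which asks whether the genes of a set move at all, stand beside it.

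Named genes were the 10 largest rises and the 10 largest falls among called genes whose 3 values in one line all lay above the 3 of the other. To these came, from each list, up to 3 called members with the largest absolute change, or the single member with the largest change where none was called, and the control genes ACTB and GAPDH. The rule gave 113 genes. Several of these are read by sets that can bind related transcripts, which holds above all for ribosomal proteins, histones and members of the MAGE family.

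The alternatives were quantile normalisation, median centring, offsets of 2 and 32, no filter and a 60% filter, no trend, array weights, the replicate number as a block, sets named as possibly cross-hybridising (_x_at and _s_at) left out, the 3' to 5' ratios as a covariate, the mean of a gene's sets, an estimated correlation, and each sample left out in turn. A set with an _x_at or _s_at name need not cross-hybridise. The wash run and the module as blocks and the contrast within each wash run were added after the files were seen.

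The steps were tested on simulated data with 13329 probe sets, 200 of them changed. At log2 changes of 0.5, 1, 2 and 4 the share recovered was 18%, 70%, 92% and 100.0%, with 6 false calls among 146. A shift of -0.3 given to the proteasome list was called, and 0 other lists were. The simulated noise was independent between probe sets, and no gene outside that list was shifted. The simulation therefore cannot show how often correlated genes give false list calls. The shares recovered also need not hold where far more probe sets differ. Figures were drawn with matplotlib 3.10.9. The precision is limited by the number of arrays, 3 per line.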

Results

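Polysomal RNA from SW480 and SW620 cells was compared on 6 arrays, 3 per line. The series concerns differences in polysomal RNA with colon cancer progression, and the question is which transcripts on polysomes differ between the line from a primary tumour and the line from its metastasis. After the scaling by the authors the median signal of the arrays ranged from 23.9 to 29.4. Across all probe sets but the controls, log2 signals correlated at 0.975 to 0.981 within a line and at 0.934 to 0.944 between lines. Probe sets are not independent replicates, so these values only describe the arrays. The median SD within a line was 0.17 on the log2 scale. No array repeated another, since at most 0.929% of probe sets had identical values on any pair of arrays. Among control sets for bacterial transcripts, 27 that were not seen above background had a median signal of 2.5 and a highest signal of 22.8, which gives the level below which a signal cannot be told from background.

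Polysomal RNA of the lines differed widely. SW620 polysomes carried far more mRNA for TOX3, a chromatin protein of the HMG-box family (signal 5.0 ± 4.16 in SW480 and 383 ± 21.1 in SW620), AKR1C3, an aldo-keto reductase of steroid and prostaglandin metabolism (5.2 ± 1.44 and 367 ± 42.2), and S100P, a calcium-binding protein (5.37 ± 3.20 and 360 ± 82.2). They carried far less mRNA for IGFBP7, a secreted binding protein for insulin-like growth factors (860 ± 137 and 4.77 ± 2.53), ANXA6, a calcium-dependent membrane-binding protein (607 ± 65.7 and 4.60 ± 3.98), and KRT5, a keratin of basal epithelium (1565 ± 148 and 30.4 ± 9.86; SD, n = 3). Of 13329 probe sets tested, 5155 differed (limma), 2610 higher and 2545 lower in SW620. At least 2-fold differences were seen in 1228 probe sets, 483 higher and 745 lower. Per gene, 3268 of 8076 differed, which is 40.5%, with 1565 higher and 1703 lower. Among all called genes neither direction can be said to prevail. With median centring 1670 genes were higher and 1387 lower, and with the lowest 60% of sets left out 1426 and 1409. Among probe sets with at least 2-fold differences, more were lower than higher under every setting that gave this count. With median centring 547 were higher and 666 lower, and with quantile normalisation 514 and 704. The values of the lines did not overlap in 48.7% of the tested probe sets, where chance gives 10% for 3 against 3, and in 97.4% of the called ones.

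The 10 largest rises, on the log2 scale, were TOX3 (4.96 ± 0.21), AKR1C3 (4.83 ± 0.15), S100P (4.79 ± 0.20), TPM2, which encodes a tropomyosin (4.71 ± 0.26), the secreted protein gene CYTL1 (4.13 ± 0.19), the ephrin ligand EFNB2 (3.96 ± 0.14), the actin-binding calponin CNN3 (3.78 ± 0.17), the hepatocyte growth factor receptor MET (3.60 ± 0.11), CEMIP, a hyaluronan-binding protein (3.50 ± 0.23), and the surface glycoprotein CD24 (3.46 ± 0.088). The highest adjusted p among them was 9.6e-08 (CEMIP, limma). The 10 largest falls were IGFBP7 (-6.10 ± 0.17), ANXA6 (-5.65 ± 0.19), KRT5 (-5.38 ± 0.16), the G protein subunit GNG11 (-5.31 ± 0.18), the transglutaminase TGM2 (-5.30 ± 0.24), IGFBP3 (-5.27 ± 0.11), KRT13 (-5.25 ± 0.22), the Wnt ligand WNT5A (-5.22 ± 0.14), KRT23 (-5.10 ± 0.087) and EPAS1, which encodes the hypoxia-inducible factor HIF-2alpha (-5.06 ± 0.24). The highest adjusted p among these was 4.3e-09 (EPAS1, limma). Several sit at background in the line where they are low, so the fold changes of TOX3, AKR1C3, S100P, TPM2, CYTL1, CNN3, CEMIP, IGFBP7, ANXA6, GNG11, IGFBP3, KRT13, WNT5A and EPAS1 depend on the offset of 8, and CYTL1 stood at 2.55 with an offset of 32. With the mean of a gene's sets MET stood at 1.93 and EPAS1 at -3.05. In the contrast within the first wash run TOX3 differed by 5.24 and IGFBP7 by -6.07, and within the other run by 4.51 and -5.97. Of the 3268 called genes, 3267 had the pooled direction in both runs. This is largely built in, since the lines did not overlap in 97.4% of the called probe sets, which fixes the direction within each run.

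**Figure D1:**
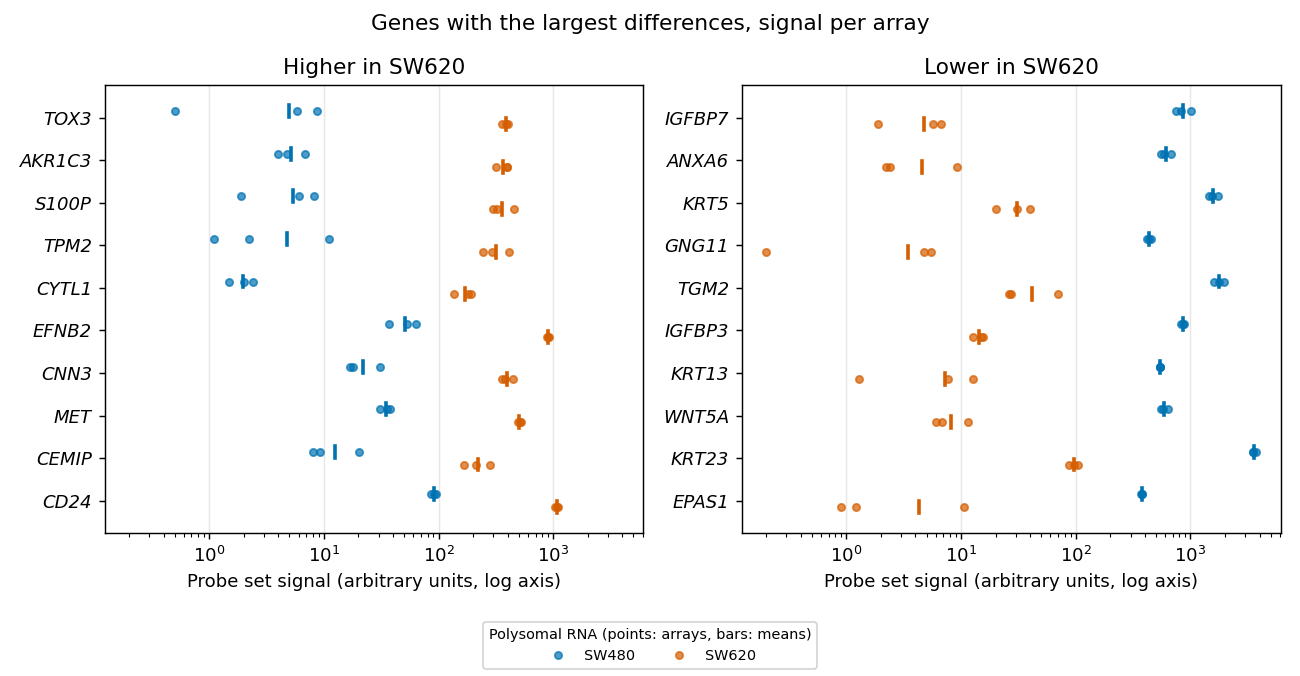
Signal of each array (points) and mean of 3 arrays (bars) for the 10 genes with the largest rises and the 10 with the largest falls, on a log axis of arbitrary signal units, SW480 in blue and SW620 in orange. By the rule of selection only genes whose arrays do not overlap between the lines could appear. IGFBP7 goes from a mean of 860 in SW480 to 4.77 in SW620.

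Of the 35 lists tested, 11 shifted by camera with the preset correlation, 3 up and 8 down in SW620. With an estimated correlation 0 lists passed after adjustment and 3 had an unadjusted p under 0.05, so every call of these lists holds only in the test with the preset correlation. The estimate was itself below 0.01 for immediate early genes (-0.027), the Wnt list (-0.030) and integrins and laminins (0.0057). For these lists a larger correlation therefore cannot be the reason that the call was lost. For the other called lists the estimate was above 0.01. By fry 22 lists moved, on balance, in one direction.

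Lists of integrins and laminins, keratins, and extracellular proteases fell. Of 19 integrin and laminin genes measured, 11 fell, 1 rose and 7 did not pass (2 rose and 11 fell when adjusted over the list alone). Among them were the integrin subunits ITGB5 (-2.92 ± 0.10), ITGA3 (-2.09 ± 0.27) and ITGAV (-1.76 ± 0.16). ITGB5 stood at -1.55 without the sets that can cross-hybridise, and ITGA3 at -1.19 with an offset of 32. The median of the list was -0.42 (camera adjusted p = 0.012; adjusted p = 0.36 with an estimated correlation), and -0.46 and -0.41 within the wash runs. Of 12 keratin and plakin genes, 6 fell and 2 rose (7 and 3 adjusted over the list alone), and the fall was carried by a few members, KRT5, KRT13 and KRT23 among them, since the median was -0.24 and the mean -1.51. The camera adjusted p was 0.019 (adjusted p = 0.37 with an estimated correlation), and the medians within the runs were -0.16 and -0.30. The keratin call was lost without the sets that can cross-hybridise (median -0.05) and without a trend. Of 25 extracellular proteases and inhibitors, 10 fell, 3 rose and 12 did not pass, with the same counts adjusted over the list alone. The protease inhibitor SERPINA1 (-2.98 ± 0.13), tissue plasminogen activator PLAT (-1.83 ± 0.19) and the cathepsin CTSL (-1.82 ± 0.16) led the list, whose median was -0.17 (camera adjusted p = 0.044; adjusted p = 0.38 with an estimated correlation), and -0.23 and -0.37 within the runs. The protease call was lost without SW480 replicate 3 (median -0.11), without SW620 replicate 1 (-0.13) and without SW620 replicate 3 (-0.24), and also with quantile normalisation (-0.13). With an offset of 32 the median was -0.11 and PLAT stood at -1.14, with median centring the median was -0.11, and with the lowest 60% left out it was -0.37.

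Signalling genes fell more often than they rose. Of 37 growth factor receptors and ligands, 22 fell, 8 rose and 7 did not pass (9 rose and 22 fell when adjusted over the list alone). The largest falls belonged to IGFBP7 and IGFBP3, which bind growth factors and are neither receptors nor ligands, and to the epidermal growth factor receptor EGFR (-4.04 ± 0.16), while MET and EFNB2 rose. The median was -0.67 (camera adjusted p = 0.012; adjusted p = 0.36 with an estimated correlation), and -0.52 and -0.71 within the runs. The main EGFR set read 242 to 263 in SW480 and 5.8 to 11.1 in SW620. Without the sets named as possibly cross-hybridising, EGFR was read by another, dimmer set, at 0.35 with an adjusted p of 0.30 (limma). The list was then not called (median -0.22). Of 20 genes of the Wnt and beta-catenin pathway, 11 fell, 5 rose and 4 did not pass, also when adjusted over the list alone. WNT5A and the hyaluronan receptor CD44 (-3.06 ± 0.12) fell, and the intestinal stem cell marker LGR5 rose from a signal of 3.13 ± 2.06 to 107 ± 3.82 (3.38 ± 0.20). The median was -0.62 (camera adjusted p = 0.028; adjusted p = 0.36 with an estimated correlation), and -0.67 and -0.65 within the runs. The Wnt call was lost without SW480 replicate 3 (median -0.56), without the sets that can cross-hybridise (-0.41) and without a trend, and without a filter on dim sets, where the list was still called, the median was -0.22. With an offset of 32 LGR5 stood at 1.98. Immediate early genes, whose mRNAs appear within minutes of stimulation, gave the lowest p of the lists. Of 24, 17 fell, 2 rose and 5 did not pass, with the same counts adjusted over the list alone. CCN1, which encodes a matrix-associated signalling protein, fell by 3.64 ± 0.19, the transcription factor FOS by 2.91 ± 0.22 and MAFF by 1.74 ± 0.10. The median was -0.79 (camera adjusted p = 0.00012; adjusted p = 0.23 with an estimated correlation), and -0.78 and -0.83 within the runs. With an offset of 32 the median was -0.51 and FOS stood at -1.60, and with the mean of its sets MAFF stood at -1.12.

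Proteasome and histone genes also fell. Of 32 proteasome genes, 17 fell, 3 rose and 12 did not pass (19 fell and 3 rose when adjusted over the list alone). The ATPase subunits PSMC4 (-1.04 ± 0.097) and PSMC2 (-0.99 ± 0.078) and the ubiquitin receptor ADRM1 (-0.98 ± 0.11) were the largest. The median was -0.25 (camera adjusted p = 0.012; adjusted p = 0.45 with an estimated correlation), and -0.18 and -0.27 within the runs. Of 14 replication-dependent histone genes measured of 50 listed, 6 fell, 1 rose and 7 did not pass, also when adjusted over the list alone. H2BC12 fell by 2.59 ± 0.089, the linker histone H1-2 by 2.46 ± 0.12 and H2BC5 by 1.54 ± 0.10. The median was -0.51 (camera adjusted p = 0.027; adjusted p = 0.36 with an estimated correlation), and -0.50 and -0.56 within the runs. Histone genes are near-identical copies, so single members are uncertain, and the list was not called without the sets that can cross-hybridise (median -0.24), while without SW480 replicate 3 its median was -0.32. It was still called, at medians from -1.24 to -0.21, under both other filters, and at -0.30 with an offset of 32 and with the 3' to 5' ratio as a covariate.

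The 3 lists that rose belong to the ribosome and the mitochondrion, and their shifts were small. Of 52 cytosolic ribosomal protein genes, 13 rose, 2 fell and 37 did not pass (9 rose and 1 fell when adjusted over the list alone). RPS28 (0.57 ± 0.13), RPS29 (0.50 ± 0.12) and RPL37 (0.49 ± 0.077) were the largest. The RPS28 and RPS29 calls were lost with the 3' to 5' ratio as a covariate. RPS29 stood at 0.32 without SW480 replicate 3, and its call and that of RPL37 were lost within the first wash run (0.30 and 0.35), while RPS29 stood at 0.86 within the other. The median was 0.14 (camera adjusted p = 0.027; adjusted p = 0.64 with an estimated correlation), and 0.094 and 0.17 within the runs. Of 59 genes of oxidative phosphorylation, 20 rose, 5 fell and 34 did not pass (21 and 5 adjusted over the list alone). The complex I subunit NDUFB8 (1.0 ± 0.082) and the ATP synthase subunit ATP5MC2 (0.99 ± 0.074) rose, and another complex I subunit, NDUFB5, fell (-0.72 ± 0.075). The ATP5MC2 call was lost without the sets that can cross-hybridise (0.16), and with the mean of a gene's sets NDUFB8 stood at 0.66 and ATP5MC2 at 0.58. The median was 0.19 (camera adjusted p = 0.029; adjusted p = 0.56 with an estimated correlation), and 0.061 and 0.21 within the runs. Of 48 mitochondrial ribosomal protein genes, 17 rose, 7 fell and 24 did not pass (17 and 8 adjusted over the list alone). MRPS27 (0.79 ± 0.087), MRPS30 (0.78 ± 0.13) and MRPS16 (0.72 ± 0.11; 0.48 within the first run) rose. The median was 0.17 (camera adjusted p = 0.044; adjusted p = 0.44 with an estimated correlation), and 0.13 and 0.21 within the runs. All 3 calls were lost with quantile normalisation (medians 0.10, 0.13 and 0.16) and without SW480 replicate 3 (0.14, 0.12 and 0.15), and that of the cytosolic ribosomal proteins also without SW480 replicate 2 (0.099). The medians of all 3 lay within the central range of random lists of equal size and brightness.

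**Figure D2:**
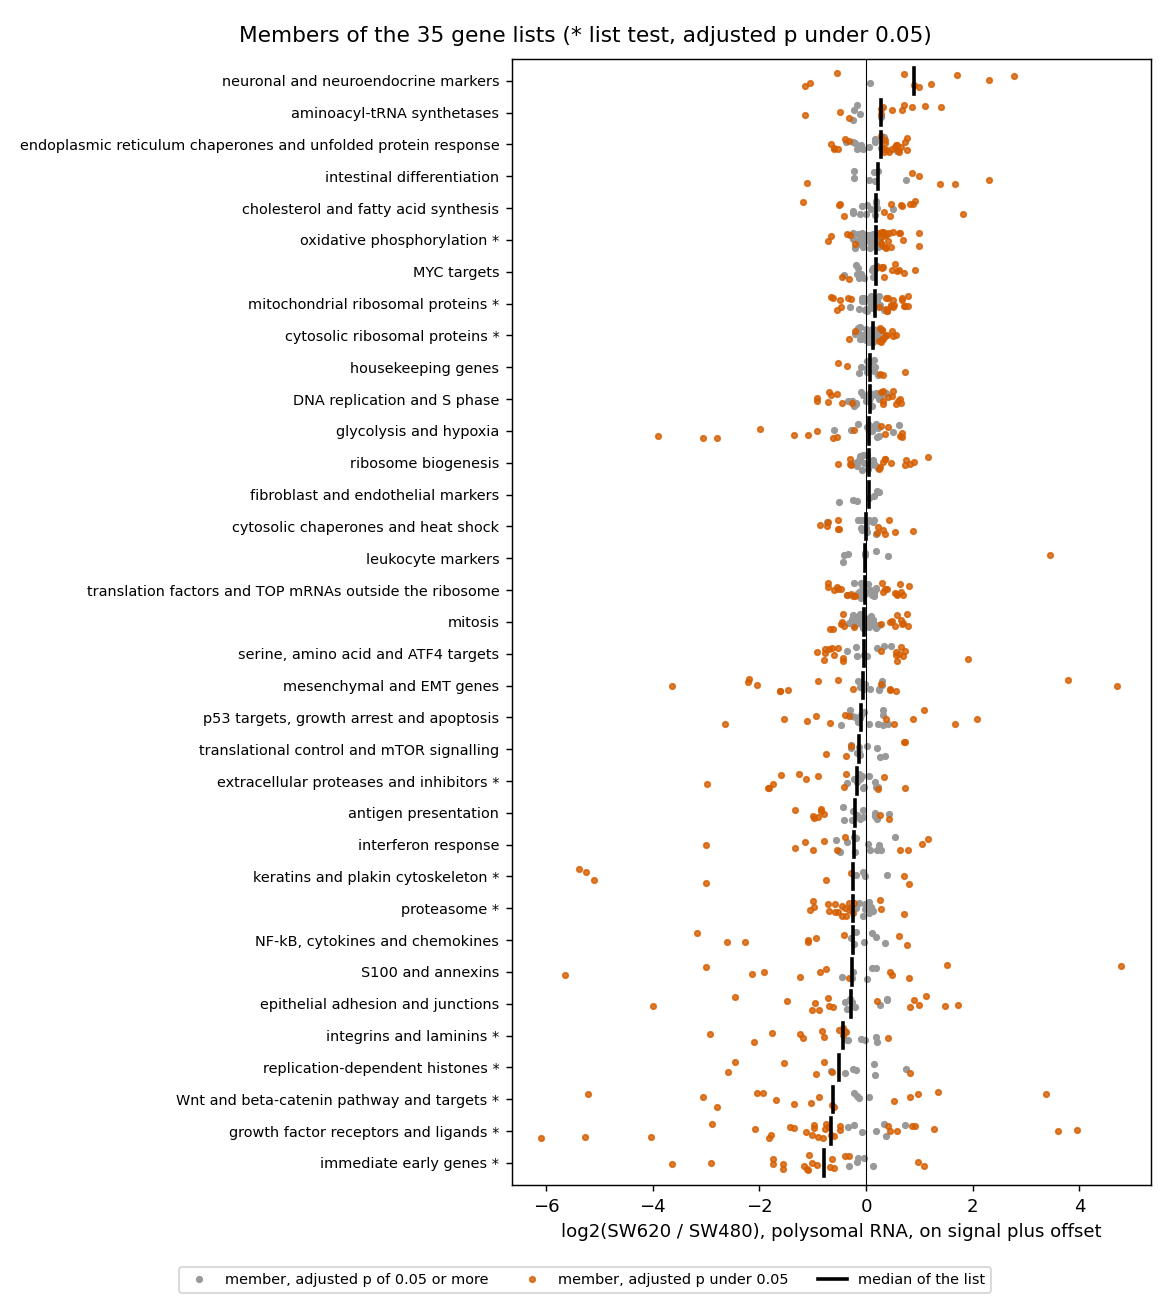
Log2 fold change of each measured member of the 35 lists on the log2(signal + 8) scale (points, orange where the member passed an adjusted p under 0.05) with the median of each list (black bars), lists ordered by median. The 11 lists with a star passed camera with the preset correlation, from immediate early genes at a median of -0.79 to oxidative phosphorylation at 0.19.

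The other lists of the translation apparatus and of growth were not called in the planned comparison, but without SW620 replicate 2 the aminoacyl-tRNA synthetases (median 0.33), ribosome biogenesis (0.10) and MYC targets (0.20) were, the last also without a filter and with the mean of a gene's sets, and the first and last within the first wash run. Among 41 translation factors and TOP mRNAs, 11 rose and 10 fell (camera adjusted p = 0.79). The initiation factor subunit EIF2S3 rose (0.81 ± 0.083), and EIF2B5 (-0.72 ± 0.11) and EIF2B4 (-0.71 ± 0.094), subunits of its exchange factor, fell. Among 15 genes of translational control and mTOR signalling, 2 rose and 3 fell (camera adjusted p = 0.88), the phosphatase subunit PPP1R15A at -0.74 ± 0.15, the mTOR inhibitor DDIT4 at 0.73 ± 0.14 and PIK3R1 at 0.71 ± 0.16. The DDIT4 call was lost within the first wash run and that of PIK3R1 within the other, and PIK3R1 stood at 0.43 without the sets that can cross-hybridise and at 0.46 with the mean of its sets. Among 17 aminoacyl-tRNA synthetases, 9 rose and 3 fell (camera adjusted p = 0.11), with AARS1 (1.41 ± 0.099) and TARS1 (1.10 ± 0.091) higher and RARS1 (-1.14 ± 0.19; -0.63 within the second wash run) lower. Among 33 genes of ribosome biogenesis, 11 rose and 4 fell (camera adjusted p = 0.16), led by GTPBP4 (1.16 ± 0.13), DDX21 (0.91 ± 0.096) and BRIX1 (0.82 ± 0.16). Among 25 MYC targets, 11 rose and 2 fell (camera adjusted p = 0.062), led by PRDX3 (0.92 ± 0.084), PAICS (0.71 ± 0.11) and SHMT2 (0.62 ± 0.075). The SHMT2 call was lost without the sets that can cross-hybridise.

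Lists of epithelial and mesenchymal character held large changes in opposite directions. Of 24 genes of epithelial adhesion, 7 rose and 9 fell (camera adjusted p = 0.56). The tight junction gene CLDN7 (-4.00 ± 0.15) and the cadherin CDH3 (-2.45 ± 0.23) fell, and the desmosomal gene PERP rose (1.72 ± 0.099). Of 27 mesenchymal genes, 6 rose and 10 fell (camera adjusted p = 0.39), with TPM2 and CNN3 up and CCN1 down. Of 13 genes of intestinal differentiation, 5 rose and 1 fell (camera adjusted p = 0.080). The enteroendocrine granule protein CHGB (2.30 ± 0.15), the microvillus protein VIL1 (1.68 ± 0.22) and the goblet cell peptide TFF3 (1.39 ± 0.18) rose. The list was called without a filter and within the first wash run, and VIL1 stood at 0.94 within the other. Of 19 S100 and annexin genes, 5 rose and 8 fell (camera adjusted p = 0.11), with ANXA6 and S100A2 (-3.0 ± 0.087) down and S100P up. Of the 44 cancer-testis genes listed only 4 passed the filter on dim sets, too few for the list test. Without that filter all 36 lists could be tested. MAGEA12 (2.37 ± 0.19) and MAGEB2 (2.02 ± 0.16) rose, and MAGEC2 stood at -0.70 ± 0.23 (limma adjusted p = 0.029), a call lost when any sample but SW620 replicate 2 was left out (-0.74 to -0.54), with the fluidics module as a block, with the 3' to 5' ratio as a covariate and within the wash run of SW480 replicate 3. With an offset of 32 CDH3 stood at -1.23, MAGEA12 at 1.49, MAGEB2 at 1.30 and MAGEC2 at -0.37.

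Cell cycle and stress lists were not called in the planned comparison. Of 40 replication genes, 11 rose and 8 fell (camera adjusted p = 0.69), RRM2 (-0.93 ± 0.074), CCNE1 (-0.92 ± 0.17) and CDC6 (-0.72 ± 0.12) the largest. RRM2 stood at -0.56 without the sets that can cross-hybridise and CDC6 at -0.44 within the first wash run. Of 40 mitosis genes, 10 rose and 7 fell (camera adjusted p = 0.79), ZWINT (0.79 ± 0.087), NEK2 (0.76 ± 0.099) and KIF11 (0.69 ± 0.11) the largest. Of 27 p53 target and apoptosis genes, 6 rose and 7 fell (camera adjusted p = 0.99). The death receptor FAS fell (-2.65 ± 0.19; -1.74 with an offset of 32), and BTG1 (2.07 ± 0.083) and CASP4 (1.68 ± 0.14) rose. Of 26 cytosolic chaperones, 7 rose and 6 fell (camera adjusted p = 0.99), with CHORDC1 (0.88 ± 0.15), DNAJB6 (-0.85 ± 0.099) and HSPA4 (-0.73 ± 0.091), the call of HSPA4 being lost without the sets that can cross-hybridise (-0.11; -0.48 with the mean of its sets), and CHORDC1 standing at 0.55 with the 3' to 5' ratio as a covariate. Of 37 endoplasmic reticulum chaperone and unfolded protein response genes, 17 rose and 6 fell (camera adjusted p = 0.051), with SSR1 (0.77 ± 0.11), PDIA4 (0.77 ± 0.10) and XBP1 (0.74 ± 0.13). The list was called without SW620 replicate 2 (median 0.30), with an offset of 32, without a filter, with the mean of a gene's sets and within the first wash run.

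Immune lists, and metabolic lists other than oxidative phosphorylation, were not called in the planned comparison either. Of 33 glycolysis and hypoxia genes, 6 rose and 10 fell (camera adjusted p = 0.51). The largest changes were falls, with the glucose transporter SLC2A3 (-3.90 ± 0.097), NDRG1 (-3.06 ± 0.15) and the peptide hormone ADM (-2.79 ± 0.12). Of 25 genes of cholesterol and fatty acid synthesis, 9 rose and 4 fell (camera adjusted p = 0.11), with the desaturase SCD (1.83 ± 0.096), INSIG2 (-1.18 ± 0.17) and HMGCS1 (0.92 ± 0.15). Of 27 serine, amino acid and ATF4 genes, 9 rose and 10 fell (camera adjusted p = 0.87), the amino acid transporters SLC38A2 (1.91 ± 0.11), SLC7A5 (-0.93 ± 0.094) and SLC1A4 (-0.79 ± 0.12) among them. Of 24 interferon response genes, 4 rose and 7 fell (camera adjusted p = 0.39), with IFITM1 (-3.01 ± 0.21), UBE2L6 (-1.33 ± 0.22) and OAS1 (1.17 ± 0.28). Of 22 antigen presentation genes, 2 rose and 7 fell (camera adjusted p = 0.13), with PSMB9 (-1.34 ± 0.15), CD74 (-0.99 ± 0.25) and TAPBP (-0.98 ± 0.27). Of 16 NF-kB, cytokine and chemokine genes, 2 rose and 7 fell (camera adjusted p = 0.077), with CXCL14 (-3.17 ± 0.21), the chemokine receptor CXCR4 (-2.61 ± 0.14) and LIF (-2.27 ± 0.24). This last list was called without SW620 replicate 2 (median -0.25) and without the sets that can cross-hybridise. CXCR4 was read by another set, at -5.13 and -5.27, without SW620 replicates 2 and 3 in turn, as its brightest set then changed, and TAPBP stood at -0.60 without SW620 replicate 3. The TAPBP call was lost within the first wash run and those of OAS1 and CD74 within the other, and with an offset of 32 OAS1 stood at 0.62, CD74 at -0.51, CXCL14 at -1.71 and LIF at -1.25. Of the 24 lists that were not called, 19 had the same counts when adjusted over the list alone.

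Lists of markers of other cell types were not called in the planned comparison. Of 8 leukocyte markers measured, 1 rose, the actin-bundling protein LCP1 (3.44 ± 0.35), and 0 fell (camera adjusted p = 0.79). Of 7 fibroblast and endothelial markers none passed (0 rose and 0 fell; camera adjusted p = 0.99), and the largest value was that of THY1, at -0.51 ± 0.22 (limma adjusted p = 0.091), which was called with the wash run as a block (-0.61). Of 11 neuronal and neuroendocrine markers, 7 rose and 3 fell (median 0.91; camera adjusted p = 0.075). The granins SCG2 (2.77 ± 0.19) and CHGB and the RNA-binding protein ELAVL2 (1.70 ± 0.34) were the largest, and colon cancer cells can themselves express granins. With an offset of 32 SCG2 stood at 1.78 and ELAVL2 at 0.91. This list was called with an offset of 32 and without SW480 replicate 1 (median 0.82), and its median was 0.32 without a filter on dim sets and 1.41 without the sets that can cross-hybridise. Of 16 housekeeping genes, 3 rose and 2 fell (camera adjusted p = 0.51), with POLR2A (0.73 ± 0.13), ALAS1 (-0.52 ± 0.10) and ACTB (-0.35 ± 0.088; limma adjusted p = 0.0062). The ACTB call was lost with median centring (-0.29), without a trend and within each wash run alone, and that of ALAS1 within the first, while GAPDH stood at 0.05 ± 0.088 (limma adjusted p = 0.71). The 3' to 5' signal ratio of a control gene, a measure of RNA integrity, overlapped between the lines. That of GAPDH was 1.07 ± 0.0792 in SW480 and 1.01 ± 0.0647 in SW620 (SD, n = 3; exact permutation p = 0.4), and that of ACTB was 1.26 ± 0.0719 and 1.25 ± 0.0374 (exact permutation p = 1). A control set for the 5' part of 18S ribosomal RNA read 501 ± 424 in SW480 and 1429 ± 607 in SW620 (exact permutation p = 0.2).

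Genes of whole chromosomes shifted as well. On chromosome 10, 127 of 313 genes rose and 33 fell (median 0.27), and on chromosome 16, 110 of 368 rose and 39 fell (median 0.15). On chromosome 19, 141 of 509 genes fell and 21 rose (median -0.16). Falls also prevailed on chromosome 3 (137 fell and 53 rose of 455, median -0.15), chromosome 9 (107 fell and 31 rose of 311, median -0.20) and chromosome 7 (35.7% fell and 16.6% rose of 373, median -0.17). These 6 of 23 chromosomes passed camera with the preset correlation, with adjusted p of 4.3e-05 for chromosome 10, 0.0027 for chromosomes 16 and 19, 0.016 for chromosome 3, 0.035 for chromosome 7 and 0.017 for chromosome 9. With an estimated correlation only chromosome 10 passed (adjusted p = 0.017), against adjusted p = 0.14 with an estimated correlation for chromosomes 3, 7, 9 and 16 and adjusted p = 0.23 with an estimated correlation for chromosome 19. Within the wash runs the medians were 0.30 and 0.23 for chromosome 10, 0.13 and 0.17 for chromosome 16, -0.15 and -0.18 for chromosome 3, -0.21 and -0.18 for chromosome 7, -0.22 and -0.25 for chromosome 9, and -0.18 and -0.21 for chromosome 19. The call for chromosome 7 was lost without a filter on dim sets (-0.08), without a trend, without the sets that can cross-hybridise and within the wash run of SW480 replicate 3, and that for chromosome 9 within the other run. Without a filter on dim sets the medians of chromosomes 9, 16 and 19 were -0.13, 0.074 and -0.10, with the lowest 60% left out that of chromosome 16 was 0.25, with median centring those of chromosomes 3, 7 and 19 were -0.086, -0.10 and -0.10, and with the 3' to 5' ratio as a covariate that of chromosome 19 was -0.11, all of them still called.

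**Figure D3:**
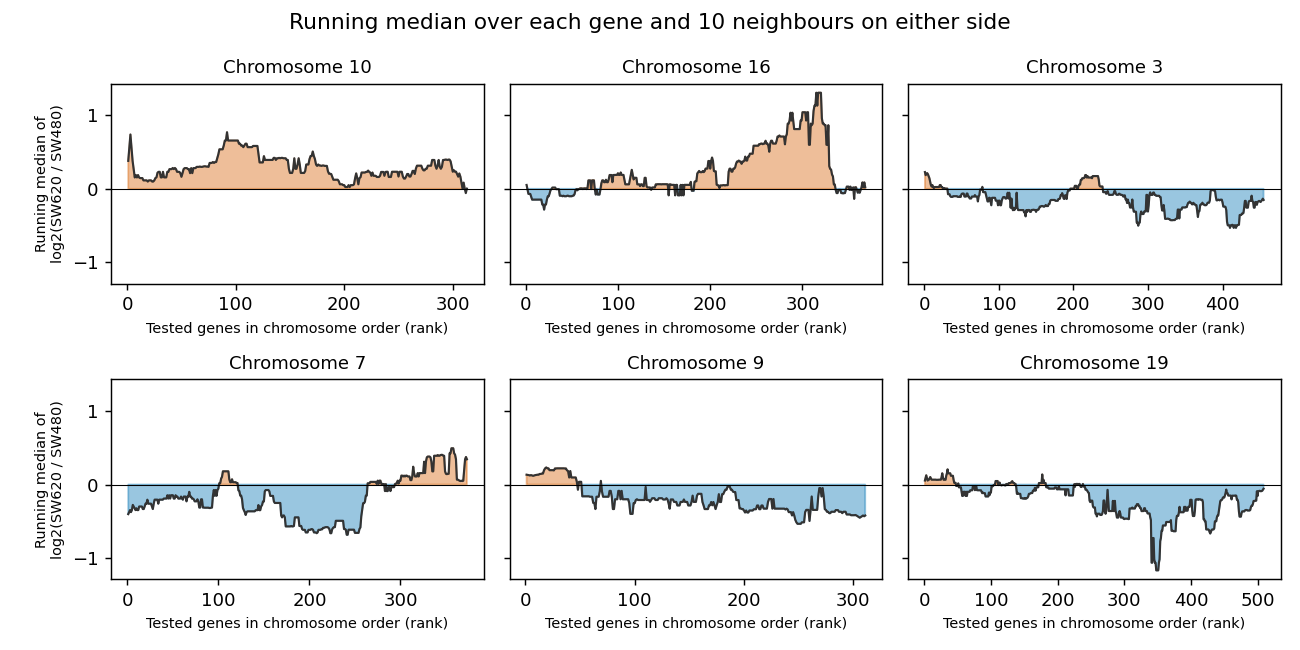
Running median of the log2 fold change over each gene and its 10 neighbours on either side, along the tested genes of 6 chromosomes in the order of assembly GRCh38.p14, by rank and not by distance. The running median reached 1.31 on chromosome 16 and -1.17 on chromosome 19, and lay above 0 for 99.7% of the genes of chromosome 10.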

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

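The tests on ribosomal RNA were chosen only after the result was seen. The others were written down before they were run. Those on single lists and chromosomes cover only ones called above, which the original plan did not single out. Control sets for ribosomal RNA, which stand outside the comparison of mRNAs, gave signals above every unspiked bacterial control on all arrays in 9 cases, and most were higher in SW620. The log2 difference was 1.74 for the 5' set of 18S RNA and 1.68 for its older counterpart, 0.56 for the middle and 0.42 for the 3' set of 28S RNA, and 0.52 for the older middle set of 18S RNA. It was 0.24 and 0.16 for the older 5' and middle sets of 28S RNA, 0.078 for the 3' set of 18S RNA and -0.091 for the older one. Sets with an array at or below the highest bacterial control were left out of the 9. Among these, the middle set of 18S RNA differed by 1.03 and the 5' set of 28S RNA by 0.72, both dim in SW480. The older 3' set of 28S RNA, at background in both lines, differed by 0.069. The arrays of SW480 spread from 180 to 981 for the 5' set of 18S RNA and those of SW620 from 808 to 2021 (exact permutation p = 0.2). The exact permutation p was 0.1, the lowest possible, for the middle set of 28S RNA and the older 18S middle and 28S 5' sets. It was also 0.1 for the left-out 18S middle and 28S 5' sets, and from 0.2 to 0.8 for the other ribosomal RNA sets. The wash run stays open, since with the array as the unit and the run as a block the mean over the 9 sets was higher in SW620 by 0.64 ± 0.14 (SE), and by 0.23 ± 0.059 without the 5' sets of 18S RNA, but each run holds 1 array of one line, and an exact permutation test over the 9 arrangements within the runs cannot go below its p of 0.11. RNA degradation stays open too, because the 3' to 5' ratio of GAPDH differed by -0.085 on the log2 scale and its ranges overlapped. More ribosomal RNA carried into the labelling, or more ribosomes per mRNA in SW620, could raise such signals. Yet the 3' sets of 18S RNA hardly moved (0.078 and -0.091), and neither explanation was tested.

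The rises of cytosolic ribosomal proteins, oxidative phosphorylation and mitochondrial ribosomal proteins may come from the brightness of their probe sets. Among 10000 random lists matched on mean signal their medians lay at percentiles 86.3, 96.0 and 91.9, inside the central range of these lists, and such bright lists had median shifts of 0.08, 0.08 and 0.06. The wash run and genes on shifted chromosomes stay open. Lists already inside that range leave little to remove, and their percentiles were 76.8, 49.5 and 81.7 within the run where each stood out less and 85.5, 96.3 and 95.0 after chromosome medians were taken off. The fall of the proteasome list runs against brightness, at percentile 0, and against the wash run, at percentiles of at most 0.21 within either run. The list also stayed called with the run as a block (median -0.22). After chromosome medians were taken off it stood at percentile 0, and its median went from -0.25 to -0.18. This argues only against shifts of whole chromosomes, since 1 median per chromosome was taken off. Shifts in stretches remain after that step and stay open for the proteasome list. Running medians reached -1.17 on chromosome 19 and -0.69 on chromosome 7. A lower proteasome mRNA load on SW620 polysomes remains a hypothesis, found and tested on the same data and not called with an estimated correlation.

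The shifts of chromosomes are not explained by brightness, as the medians of chromosomes 3, 7, 9 and 19 lay at percentile 0 and those of chromosomes 10 and 16 at percentile 100 of matched random lists. A candidate explanation is gene dose that differs between the lines in stretches. Neighbouring genes moved together more than in 1000 shuffles of each chromosome, with permutation p of 0.013 for chromosome 3, 0.001 for chromosomes 7, 16 and 19, which is the smallest the shuffles can give, 0.002 for chromosome 9 and 0.043 for chromosome 10. Clusters of genes regulated together would give this too, and DNA copy number was not analysed here.

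With 3 samples against 3 there are 10 splits of the samples, too few for a share under 0.05, and in each case only 1 split, the real one, gave a result as large. The real split gave 5155 probe sets, 1228 probe sets with at least 2-fold differences, 3268 genes, 11 lists and 6 chromosomes, and the highest of the other splits gave 0, 0, 0, 7 and 2. At an unadjusted p under 0.05 in limma or camera the highest of the other splits gave 341, 14, 208, 12 and 7, and the real one 6177, 1229, 3846, 16 and 12. Every other split puts both lines in each group, so the difference between the lines widens the spread within groups. Low counts of probe sets and genes in those splits are therefore built in, and their contrast with the real split decides nothing.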

How the results depend on the processing

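The wash run and module settings and the estimated correlation for chromosomes were chosen only after the data were seen, and the rest were planned. No probe set was called in the opposite direction under any setting. Counts within 1.5 times the main count are not listed, and the cause of the changes was not tested unless stated. Without the sets that can cross-hybridise, 6198 probe sets and 4928 genes were left to test. Of these 2189 probe sets, 565 with at least 2-fold differences, and 1883 genes were called. In this setting 4 lists were called, and EGFR, read by another set, stood at 0.35. Calls lost in this setting can come from fewer sets and members as well as from cross-hybridisation. Within the first wash run alone, with 3 samples and the spread pooled over both runs, 3184 probe sets and 2164 genes were called, and with an offset of 32, which shrinks dim folds, 723 probe sets reached 2-fold. The number of lists was 7 with quantile normalisation (0 up and 7 down), 7 with the lowest 60% left out, 5 without a trend, 7 with the 3' to 5' ratio as a covariate and 0 with an estimated correlation. The number of chromosomes was 11 with the lowest 60% left out and 1 with an estimated correlation. With 1 sample left out the counts ranged from 4264 to 4942 probe sets, 1230 to 1309 with at least 2-fold differences, 2716 to 3183 genes and 6 to 16 lists, the 6 without SW480 replicate 3, and stayed at 6 chromosomes. With median centring 57.4% of called probe sets were higher in SW620, against 50.6%. Scaling moved the median of all genes from -0.0047 to at most 0.058.

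No sign of pairing by replicate number was seen, as same-numbered samples deviated together at 0.087, -0.092 and -0.026 across probe sets. So few samples cannot show that pairing is absent. Pairs of the 2 lines within a wash run stood at -0.026 to 0.18, and pairs from different runs at -0.17 to 0.035. The fit with the replicate number as a block called 4981 probe sets, 1229 with at least 2-fold differences, 3152 genes, 11 lists and 6 chromosomes, and changed no call of a named gene, list or chromosome. The wash run as a block gave 5137 probe sets and 3259 genes.

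The calls of immediate early genes, integrins and laminins, and the proteasome were kept in all settings with a preset correlation. The 3 rising lists and the proteases were also no longer called with the lowest 60% left out, without a trend, without sets that can cross-hybridise, with the 3' to 5' ratio as a covariate and within the first wash run, and all of these but the cytosolic ribosomal proteins with array weights. Chromosomes 1, 6, 18, 21 and X were called with the lowest 60% left out, and chromosome 12 with the mean of a gene's sets. Among named genes, calls of ATP5MC2 (0.17), HSPA4 (-0.11), SHMT2 (0.25) and RPS28 (0.43) were lost without sets that can cross-hybridise, and those of RPS28 (0.40) and RPS29 (0.28) with the covariate. Signals under about 22.8 are not above background, so fold changes against them are limited by the offset.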

Other observations

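All gene groups in this part were chosen only after their values were seen. Targets of the Hippo pathway's effectors YAP and TEAD were lower in SW620. Of 15 measured genes of a list of 22 such targets, 10 fell and 1 rose, with a median of -1.49. CRIM1 (-3.63), NT5E (-3.98), AMOTL2 (-1.49) and F3 (-1.52) were among those that fell, besides CCN1 and IGFBP3. The camera adjusted p was 1.4e-05, and adjusted p = 0.024 with an estimated correlation, over 3 lists chosen in this way. Lower YAP and TEAD activity in SW620 may lie behind this, but the test cannot decide. The list was drawn up from genes already seen to fall, so a low median and a low p were built in. The median stood at percentile 0 of 10000 random lists matched on signal, which is no support for the same reason. It did so in the pooled data, where their central range was -0.32 to 0.26, and within both wash runs. The same limit holds for the 9 members that stand on no fixed list, whose median was -1.39, while 6 also stand on fixed lists.

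Beta-tubulin genes formed another group. Of 6 measured, 5 fell and 0 rose (median -1.98; camera adjusted p = 2.8e-05; adjusted p = 0.10 with an estimated correlation). TUBB2A went from a signal of 1287 ± 26.2 to 151 ± 15.6, TUBB2B differed by -3.35 and TUBB6 by -2.80, and their sequences are close enough that the sets can bind each other's transcripts. Enzymes of steroid, retinoid and prostaglandin metabolism changed in both directions, 8 up and 13 down of 26 (camera adjusted p = 0.16). AKR1C3, AKR1C1 (1.61) and HSD11B2 (1.89) rose, and HPGD (-3.08), CYP24A1 (-3.06), ALDH1A3 (-2.69) and CYP26A1 (-2.48) fell. As single genes, and not as a tested group, 4 more were higher in SW620, with the kinase LCK at 35.6 ± 7.37 and 410.5 ± 23.7, MYB at 38.9 ± 8.80 and 329 ± 13.7, TRBC1 at 123 ± 9.98 and 638 ± 47.3, and SIT1 at 7.80 ± 1.87 and 45.2 ± 2.38, while the leukocyte markers fixed beforehand were not called as a list, and 7 of 8 did not pass.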
